A study of Mus musculus with 5 samples.

How the data were processed

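RNA from PDGFRa-positive cells of Balb/c mouse mammary glands was sequenced in 5 libraries, 2 from nulliparous females and 3 from females 6 days after weaning of their pups. Cells came from glands 4 and 5 and were sorted by fluorescence for PDGFRa, a receptor used as a surface marker of fibroblasts, then frozen before RNA extraction, per the labels' protocols. Libraries were made from total RNA with the TruSeq RNA kit, version 2, which does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The series describes the libraries of each group as biological replicates.

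Base calls were converted with bcl2fastq and reads were aligned with STAR 2.4.2a to the mouse genome build GRCm38, per the submitters' processing notes. The counting tool, the gene annotation, the scaling between libraries and the offset are not given in the sources used here. The authors deposited 1 table of log2 values, with 45706 rows named by Ensembl identifier and 1 column per library. The values ran from 3.44 to 21.16. The 17395 rows without reads in any library sat near 3.57 in each column, which corresponds to an offset of about 11.8 on the unlogged scale. The deposited values are therefore read here as the log2 of a scaled count plus this offset, and a log2 difference understates the change of a weakly expressed gene. Some values in rows with reads in other libraries lay lower, down to 3.44 in nulliparous replicate 1, so values depend on the other libraries of their row. The method of this adjustment is unknown.

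The unlogged columns summed to about 37600000 and 38900000 in nulliparous replicates 1 and 2, and to about 43000000, 42600000 and 41000000 in involution replicates 1, 2 and 3. The step that 1 read adds, taken from rows with 1 read in a single library, gave estimated depths of about 40400000, 38100000, 43100000, 44300000 and 37600000 reads in the same order. Between 2.78% and 86.3% of values of 6 to 20 reads lay within 0.1 of a whole read, depending on the library. Whole reads were not recovered, and no test that needs counts was run. Sampling error of single genes can therefore only be judged from the spread between libraries.

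The file paired 22982 rows with a usable symbol. In 27 other rows a spreadsheet had turned the symbol into a date. Symbols of 22302 rows that lacked one or held a date came from the GENCODE M21 annotation of GRCm38 by Ensembl identifier, and 422 rows kept their identifier only. Coordinates are those of GENCODE M21 on GRCm38, 1-based.

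The groups were compared gene by gene with limma 3.58.1 in R 4.3.3, on the deposited log2 values of all 5 libraries, with a moderated two-sided test whose prior variance followed the mean, and Benjamini-Hochberg adjustment with a threshold of 0.05. The test, the filters, the gene lists and the rule for the named genes were fixed before the data were examined. The filter asked for a mean of at least log2 of 10, which is 3.32. This lies below the value of a row without reads, because the offset was not known, so the filter removed only the 17395 rows without reads and left 28311 genes. A filter of 10 units above the offset, a mean of at least 4.45, left 15912 genes. It was chosen after seeing the data, and its counts of all genes and of list members stand beside the planned ones. The prior variance trend runs steeply upward at the top of the range. Over the 57 genes with a mean of at least 16 the median prior SD was 0.366 and the median residual SD 0.145, so the test loses power for some of the most abundant transcripts. Of these 57 genes 5 passed with the trend and 7 without it.

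Gene lists were tested with camera of limma at a preset correlation of 0.01, two-sided, adjusted within each kind of list. There were 18 lists of stromal biology, 14 lists of markers of other cell types and 3 lists of RNA quality and dissociation. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. Genes were named by 4 rules. The first named Pdgfra, Col1a1, Ptgs2 and Cxcl12. The second took the 6 largest rises and the 6 largest falls past the threshold whose groups did not overlap and whose higher mean was at least 6.32, leaving out predicted genes, pseudogenes and antigen receptor segments. The third took the 2 members of each biology list with the smallest p, or 4 where more than 4 passed. The fourth took the most abundant member and the member with the smallest p of each marker or quality list. Other genes named in the text were chosen after their values were seen.

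The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among the 28311 genes of the comparison of involution with nulliparous glands. The planned filter recovered 32% and 70% of them, with 6 unchanged genes among 108 called. The offset filter, on 15907 genes of the simulation, recovered 55% and 85%, with 6 unchanged genes among 146 called. A raised list gave an adjusted p of 1.12e-09 by camera in limma, and 0 of 17 other lists were called. Noise was drawn independently for each gene, and changed genes had a mean of at least 6.32. The simulation therefore cannot show how camera treats lists with correlated members, or how weakly expressed genes fare. In the data the estimated correlation ran from -0.118 (skeletal muscle) to 0.974 (epithelial cells) over the lists.

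Alternatives were a replicate block, 5 other filters, an added constant, removal of the offset, 3 scalings, other prior settings, library weights, covariates for epithelial and macrophage markers, other thresholds, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Values of some single genes are not reported here, while counts and list tests include them.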

Results

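Gene expression was measured by RNA sequencing in PDGFRa-positive mammary fibroblasts of Balb/c mice. The samples were nulliparous glands with 2 libraries and glands at day 6 after weaning with 3 libraries. Weaning starts involution, in which the milk-producing epithelium dies back and the gland is remodelled. Unlogged totals ran from about 37600000 to 43000000 per library, and 3 collagen transcripts, Col3a1, Col1a1 and Col1a2, took 8.55% to 11.8% of them. Libraries of the same group correlated across genes at a Pearson r of 0.981 to 0.990, and libraries of different groups at 0.960 to 0.974. Genes are not independent replicates, so these coefficients only describe the libraries. The first principal component held 59.6% of the variance and separated the groups. The second held 25.9% and set libraries of the same group apart. On it replicate 1 stood at 19.6 in the nulliparous and 31.4 in the involution group. Nulliparous replicate 2 stood at -26.4, and involution replicates 2 and 3 at 4.1 and -28.7.

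The series asks how fibroblast expression at involution day 6 differs from that of the nulliparous gland. The groups also differ in pregnancy and lactation, and the series holds neither lactating glands nor parous glands after regression. Effects of pregnancy, lactation and involution therefore cannot be told apart. Cells sorted from the involuting gland had more RNA of single genes of matrix proteases, chemokines, cytokines and the interferon response, and less RNA of 9 Wnt and growth factor genes, while 3 growth factor genes rose. The lists of the first 4 groups were higher in camera of limma at the preset correlation, and did not pass with an estimated correlation (adjusted p from 0.159 to 0.285). They passed by fry, which does not set a list against other genes (adjusted p from 0.00295 to 0.0262). The Wnt list was lower in camera at the preset correlation (adjusted p = 0.00237) and by fry (0.0262), and did not pass in camera with an estimated correlation (0.319). The acute-phase gene Saa3 rose by 6.37 ± 0.43 (log2 difference ± SE, n = 2 and 3), the collagenase gene Mmp13 by 5.91 ± 0.52 and the chemokine gene Ccl8 by 4.65 ± 0.19. The EGF receptor ligand gene Areg fell by 5.62 ± 0.65 and the heparin-binding growth factor gene Ptn fell by 4.13 ± 0.50. For Areg and Ptn, fibroblasts and epithelial cells left in the sort could not be told apart as the source of the RNA. Cxcl12, which encodes a chemokine of stromal cells, rose 3.67-fold. The receptor gene used for the sort, Pdgfra, stood at 15.90 ± 0.04 (SD, n = 2) in nulliparous and 15.89 ± 0.20 (SD, n = 3) in involution libraries.

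Of 28311 genes tested, 322 were higher and 235 lower at involution day 6 by the moderated test of limma with Benjamini-Hochberg adjustment, 179 and 123 of them by at least 2-fold. With the offset filter, chosen after seeing the data, 1058 were higher and 742 lower of 15912, and 508 genes were called with both filters. Groups did not overlap for 47.0% of these 15912 genes, against 20% by chance. Without any 1 of the 5 libraries, 0 genes passed in limma with the planned filter, while 4489 to 5407 genes had an unadjusted p under 0.05. With the offset filter the counts without 1 library ran from 296 to 786 higher and from 208 to 483 lower, lowest without nulliparous replicate 1.

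The 6 largest rises past the threshold were in Saa3, Mmp13, Reg1, Ccl8, Atp6v0d2 and Plxdc1. Saa3 lies on chromosome 7 from 46711998 to 46715700, and its mean went from 6.12 ± 0.11 (SD, n = 2) to 12.49 ± 0.70 (SD, n = 3), with adjusted p = 0.0319 in limma. Mmp13, on chromosome 9 from 7272514 to 7283331, went from 4.51 ± 0.55 to 10.42 ± 0.74, adjusted p = 0.0359 in limma. Reg1, a secreted lectin gene on chromosome 6 from 78422711 to 78428667, was near the value of a gene without reads in nulliparous libraries, at 4.11 ± 0.08, and reached 8.85 ± 0.10 (adjusted p = 0.0271 in limma). Ccl8, on chromosome 11 from 82115185 to 82116799, went from 7.96 ± 0.29 to 12.62 ± 0.23 (adjusted p = 0.0271 in limma). Atp6v0d2, a subunit gene of the proton pump of lysosomes, lies on chromosome 4 from 19876841 to 19922605 and rose by 4.50 ± 0.26. Plxdc1, on chromosome 11 from 97923238 to 97986444, rose by 4.18 ± 0.48. The nulliparous means of Mmp13, Reg1 and Atp6v0d2, 4.51, 4.11 and 3.91, were near the value of a gene without reads, so their rises are understated. With the offset removed and 1 added, which was chosen after seeing the data, they rose by 6.92, 6.12 and 6.32, and Saa3 by 6.61, so the order of the rises depends on the offset.

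The 6 largest falls were in Areg, Adamts18, Ptn, Abcc8, Nrxn3 and Aoc1. Areg, on chromosome 5 from 91139599 to 91148432, went from 10.15 ± 1.33 to 4.53 ± 0.42, adjusted p = 0.0451 in limma. Adamts18, a secreted metalloprotease gene on chromosome 8 from 113697126 to 113848738, went from 10.45 ± 0.28 to 5.63 ± 0.21 (adjusted p = 0.0271 in limma). Ptn, on chromosome 6 from 36714929 to 36810220, went from 11.92 ± 0.57 to 7.79 ± 0.71 (adjusted p = 0.046 in limma). Abcc8, a subunit gene of a potassium channel on chromosome 7 from 46104523 to 46180033, fell by 3.63 ± 0.32. Nrxn3, a cell adhesion gene on chromosome 12 from 88722876 to 90334935, fell by 3.43 ± 0.38. Aoc1, an amine oxidase gene on chromosome 6 from 48872896 to 48909188, fell by 3.13 ± 0.30. The involution means of Abcc8 and Aoc1, 3.64 and 3.63, were close to 3.57, the value of a gene without reads, and those of Areg and Nrxn3, 4.53 and 4.13, were near it, so these falls are understated. With the offset removed and 1 added, Areg, Abcc8, Aoc1, Adamts18, Nrxn3 and Ptn fell by 6.59, 6.53, 6.09, 5.16, 4.79 and 4.21, so the order of the falls depends on the offset too.

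**Figure D1:**
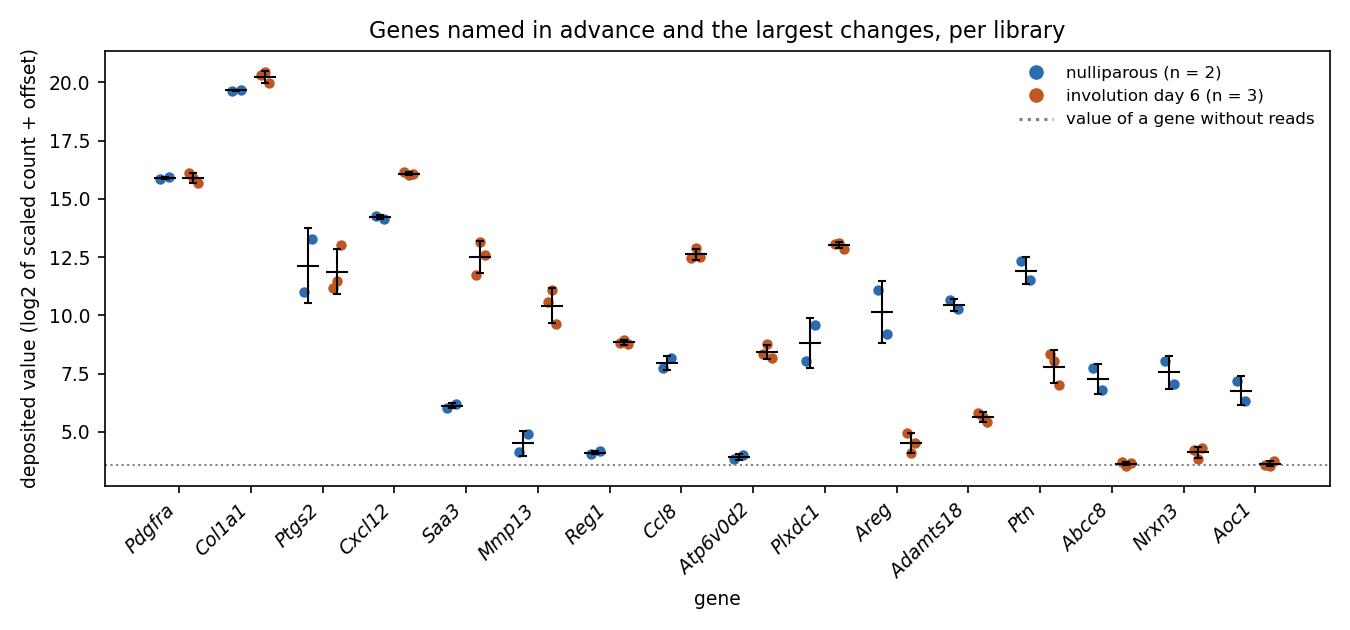
Deposited log2 values (vertical axis) of the 4 genes named in advance and the 12 largest changes (horizontal axis) in the 2 nulliparous and 3 involution day 6 libraries. Points are libraries, black marks are group means with SD, and the dotted line is the value of a gene without reads. The involution libraries lie between 11.75 and 13.13 for Saa3, above both nulliparous libraries.

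Among 42 genes of matrix proteases and their inhibitors, 9 rose, 2 fell and 31 did not pass, while 23 and 4 passed when adjusted over the list alone and 20 and 4 with the offset filter. The list was higher than other genes by camera in limma (adjusted p = 5.14e-07, and adjusted p = 0.237 with an estimated correlation). It also passed upward by fry (adjusted p = 0.00996). Its median difference was 0.86. Besides Mmp13, the urokinase gene Plau rose 7.14-fold, Ctsk, a collagen-cleaving cathepsin gene, 5.57-fold, Adamts15 3.27-fold and Mmp27 3.17-fold. Mmp11 and Mmp3, chosen after their values were seen, rose 14.9-fold and 4.22-fold. The 2 members that fell were Adamts9, by 1.53, and Mmp16, by 1.27. Of the 31 genes of collagen folding and crosslinking, 3 rose and 0 fell, while 7 and 2 passed when adjusted over the list alone and 6 and 2 with the offset filter. The 3 were Plod1 (2.89-fold), which encodes a lysyl hydroxylase, Lox (3.63-fold), a crosslinking oxidase gene, and Adamts2 (2.35-fold), which encodes a procollagen peptidase. The list as a whole did not pass in camera of limma (adjusted p = 0.178), but passed upward by fry (adjusted p = 0.0481).

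Structural matrix genes were divided. Of 11 fibrillar collagens, 0 rose and Col27a1 fell by 0.74 ± 0.08, the same 1 gene as when adjusted over the list alone, and 0 and 1 with the offset filter, and the list had an adjusted p of 0.663 in camera of limma. Col1a1, on chromosome 11 from 94936224 to 94953042, was at 19.66 ± 0.02 (SD, n = 2) and 20.24 ± 0.26 (SD, n = 3), a difference of 0.59 that did not pass (adjusted p = 0.832 in limma). At that level the prior SD was 2.23 against a residual SD of 0.211, and without the trend in the prior the SE was 0.170 and the adjusted p 0.175 in limma. Col11a1 differed by 1.49 without passing. Of 33 other collagens, Col25a1 fell by 2.69 ± 0.22 and 0 rose, 2 higher and 5 lower when adjusted over the list alone and 3 and 5 with the offset filter, with a list adjusted p of 0.0534 in camera of limma. Col6a5 was higher by 1.64 with an adjusted p of 0.0548 in limma, and 0.00683 with the offset filter. That list passed under each of the 3 other scalings, at adjusted p of 0.0144, 0.00844 and 0.00194 in camera, and without nulliparous replicate 2 or involution replicate 1 or 2, with a range from 0.00194 to 0.446 over all alternatives. Of 50 matrix glycoproteins and proteoglycans, 4 rose and 1 fell, 10 and 5 when adjusted over the list alone and 10 and 3 with the offset filter (camera adjusted p = 0.214 in limma). Smoc2 rose 4.17-fold, Fbln7 3.61-fold, Thbs2 3.08-fold and Fbln2 2.89-fold, and Vtn, the vitronectin gene, fell by 1.84.

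Lists of inflammatory genes were higher at the preset correlation of camera and did not pass with an estimated correlation. The estimate was -0.0172 for cytokines, 0.0259 for complement, 0.031 for chemokines and 0.316 for the interferon list. For the first 3 it lay near the preset 0.01, so the loss does not show that their members were correlated. By fry the chemokine, cytokine, complement and interferon lists passed upward (adjusted p = 0.00996, 0.00295, 0.0264 and 0.0262). Of 34 chemokines, Ccl8, Cxcl12 and Ccl11 rose and 0 fell, 6 and 0 when adjusted over the list alone and 7 and 0 with the offset filter (camera adjusted p = 9.33e-05 in limma, and adjusted p = 0.237 with an estimated correlation). Cxcl12, on chromosome 6 from 117168535 to 117181367, went from 14.21 ± 0.08 (SD, n = 2) to 16.09 ± 0.07 (SD, n = 3), adjusted p = 0.0319 in limma. Of 50 cytokines and inflammatory mediators, 5 rose and 0 fell, 13 and 1 when adjusted over the list alone and also with the offset filter (camera adjusted p = 3.39e-06 in limma, and adjusted p = 0.159 with an estimated correlation). Besides Saa3 these were Osmr, a receptor gene for oncostatin M (2.26-fold), Mif (2.74-fold), Cd274, which encodes the checkpoint ligand PD-L1 (1.66-fold), and Il10 (3.06-fold). Of 26 complement genes, C2 rose 2.19-fold and 0 fell, 10 and 3 when adjusted over the list alone and 8 and 3 with the offset filter (camera adjusted p = 0.00127 in limma, and adjusted p = 0.237 with an estimated correlation). C1rb was higher by 0.81, with adjusted p = 0.0525 in limma, and 0.00983 with the offset filter. Of 46 interferon response genes, 6 rose and 0 fell, 26 and 1 when adjusted over the list alone and 19 and 0 with the offset filter (camera adjusted p = 4.28e-16 in limma, and adjusted p = 0.285 with an estimated correlation). Ifit3 rose 2.35-fold, B2m, the light chain gene of MHC class I, 2.35-fold, Tapbp 1.79-fold and Gbp7 1.52-fold. The mean of macrophage markers, of which 0 of 14 passed and 2 rose with the offset filter, was 8.22 and 7.37 in nulliparous and 9.65, 9.05 and 8.28 in involution replicates 1, 2 and 3.

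Ptgs2, which encodes cyclooxygenase 2 and lies on chromosome 1 from 150100031 to 150108227, was at 12.13 ± 1.61 (SD, n = 2) and 11.88 ± 0.98 (SD, n = 3). The difference of -0.25 ± 0.93 was within the spread between libraries (adjusted p = 0.931 in limma). With covariates added after seeing the data it passed in opposite directions, at 1.84 with the macrophage marker mean (adjusted p = 0.0214 in limma) and at -1.61 with the epithelial marker mean (adjusted p = 0.0211 in limma). Over all alternatives the adjusted p ran from 0.0211 to 0.986. Of 27 genes of prostaglandin synthesis and receptors, the secreted phospholipase gene Pla2g2e rose 7.82-fold and 0 fell, 4 and 2 when adjusted over the list alone and 4 and 1 with the offset filter (camera adjusted p = 0.149 in limma). The prostaglandin E synthase gene Ptges was higher by 0.59, with adjusted p = 0.0528 in limma, and 0.0129 with the offset filter.

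Wnt and growth factor genes held 9 of the 235 falls. Of 41 Wnt ligands and modulators, 0 rose and 6 fell, 3 and 10 when adjusted over the list alone and also with the offset filter (camera adjusted p = 0.00237 in limma, and adjusted p = 0.319 with an estimated correlation). By fry the list passed downward (adjusted p = 0.0262). Without nulliparous replicate 2 the list had an adjusted p of 0.0834 in camera of limma, and over all alternatives the adjusted p ran from 0.000116 to 0.319. Wnt4 fell by 2.61 ± 0.15, Wnt6 by 2.13 ± 0.22, Tcf7, a transcription factor gene of the pathway, by 2.00 ± 0.20, and Wnt5a by 1.08 ± 0.12. Of 47 growth factors acting on epithelium or vessels, 3 rose and 3 fell, 7 and 8 when adjusted over the list alone and 5 and 8 with the offset filter (camera adjusted p = 0.571 in limma). Besides Areg and Ptn, Fgf10, a mesenchymal ligand for epithelial receptors, fell by 2.28 ± 0.16. The members that rose included Vegfb (2.54-fold) and Mdk (3.05-fold). Of 31 genes of hormone receptors and the IGF axis, 0 rose and 2 fell, 1 and 3 when adjusted over the list alone and 1 and 4 with the offset filter (camera adjusted p = 0.135 in limma, and 0.0481, 0.03 and 0.0107 under the 3 other scalings, from 0.0107 to 0.426 over all alternatives). Pappa, a protease gene that acts on IGF binding proteins, fell by 2.44 ± 0.25 and Igfbp3 by 1.36 ± 0.11. Epithelial markers, of which 0 of 15 passed with the offset filter and without it, had means of 10.41 and 8.98 in nulliparous and 9.51, 8.38 and 7.22 in involution libraries.

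Of 24 contractile myofibroblast genes, 0 rose and Myl9 fell by 1.23 ± 0.16, again 0 and 1 when adjusted over the list alone and 0 and 3 with the offset filter. Smtn differed by -0.49 (adjusted p = 0.102 in limma, and 0.0386 with the offset filter). The list had an adjusted p of 0.0567 in camera of limma and passed under each of the 3 other scalings, at 0.0144, 0.0062 and 0.00457, with the replicate block (0.00741) and without involution replicate 1 (0.00791), with a range from 0.000158 to 0.605 over all alternatives. Of 32 TGF-beta pathway genes, Tgfb1 rose 2.14-fold, Pmepa1 rose 1.72-fold and Ltbp4 fell by 1.26, 3 and 3 when adjusted over the list alone and 4 and 4 with the offset filter (camera adjusted p = 0.656 in limma, upward, while the median was -0.03, and from 0.0435 to 0.868 over all alternatives). Of 33 adipogenic and lipid handling genes, 0 rose and Elovl6, a fatty acid elongase gene, fell by 0.79 ± 0.08, 3 and 5 when adjusted over the list alone and 2 and 4 with the offset filter (camera adjusted p = 0.571 in limma). Pparg was higher by 0.35, with adjusted p = 0.06 in limma, and 0.0511 with the offset filter. Of 23 progenitor and universal fibroblast genes, Entpd2 rose 2.58-fold, Pdpn 2.60-fold and Cd9 1.36-fold, and Penk, the proenkephalin gene, fell by 2.15 ± 0.20, with 3 and 2 when adjusted over the list alone and also with the offset filter (camera adjusted p = 0.687 in limma). That list passed in opposite directions with the covariates added after seeing the data, downward with the epithelial marker mean (adjusted p = 0.032) and upward with the macrophage marker mean (0.0349), and its adjusted p ran from 0.032 to 0.974 over all alternatives. Of 50 cell cycle genes, 0 rose and 0 fell, also when adjusted over the list alone, and 1 and 0 with the offset filter (camera adjusted p = 0.178 in limma). The cell cycle list was higher past the threshold without nulliparous replicate 1 (adjusted p = 0.000134) and without involution replicate 2 (0.00553), and its adjusted p ran from 0.000134 to 0.928 over all alternatives. The smallest p in that list belonged to Ccne1, which was higher by 0.85 with an unadjusted p of 0.0135 and an adjusted p of 0.132 in limma, and 0.0495 with the offset filter.

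**Figure D2:**
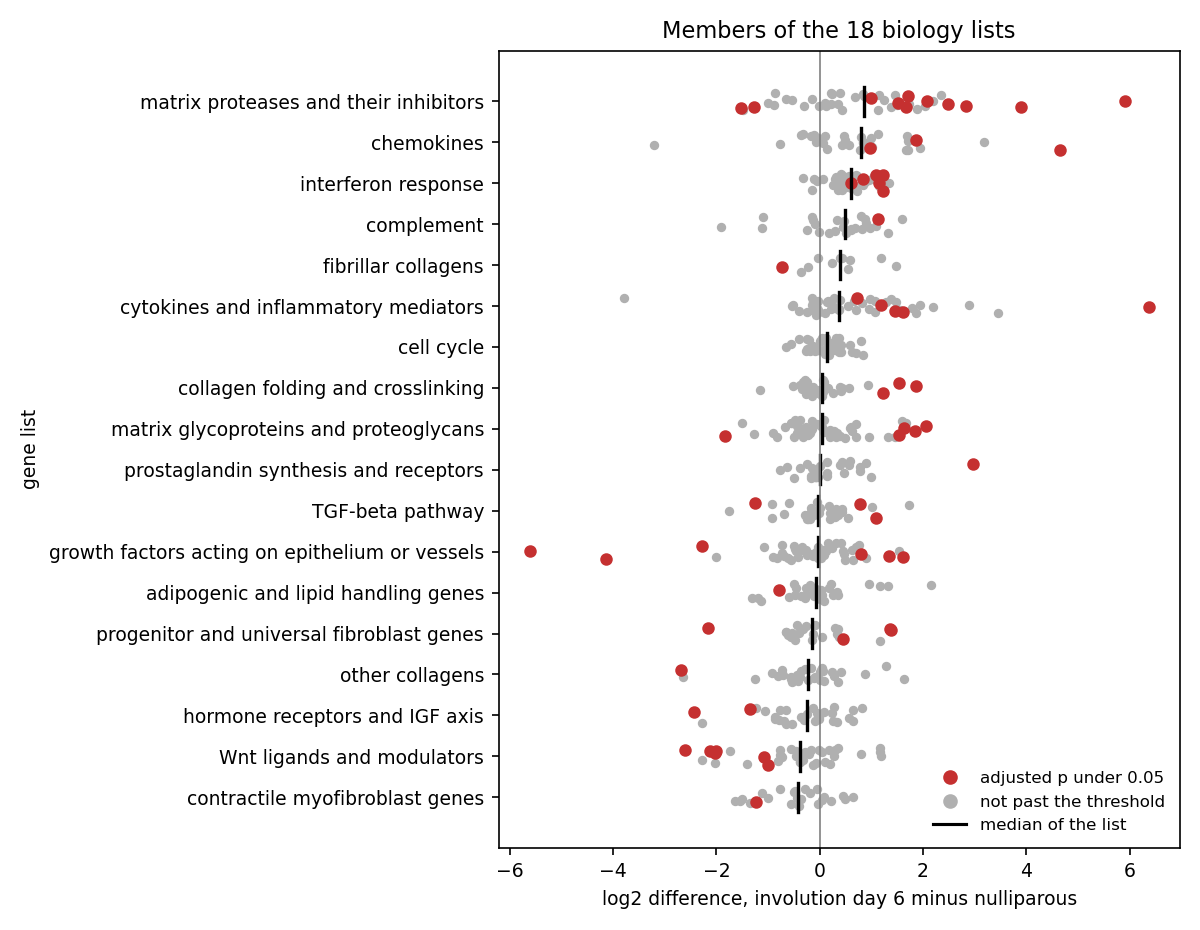
Log2 difference between involution day 6 and nulliparous libraries (horizontal axis) for each measured member of the 18 biology lists (vertical axis). Red points have an adjusted p under 0.05 in limma, grey points do not, and black lines are list medians, which run from -0.41 for contractile myofibroblast genes to 0.86 for matrix proteases and their inhibitors.

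Markers of other cell types were present in the sorted libraries. Of 14 macrophage markers, 0 passed, while the list was higher in camera of limma (adjusted p = 0.000174, and adjusted p = 0.7 with an estimated correlation), and Lyz2 was higher by 2.12 and Adgre1 by 1.64. These were the 2 macrophage markers that passed with the offset filter (adjusted p = 0.0398 and 0.0365 in limma). The 10 genes of antigen-presenting cells had 0 past the threshold and a list adjusted p of 0.0263 (adjusted p = 0.7 with an estimated correlation in limma), with Cd74 and Itgax higher by 1.16 and 2.35, of which Itgax passed with the offset filter (adjusted p = 0.0382 in limma). Of 8 neutrophil markers 0 passed, with a list adjusted p of 0.041 (adjusted p = 0.7 with an estimated correlation in limma) and Mmp8 higher by 2.04, which passed with the offset filter (adjusted p = 0.00794 in limma). Of 8 milk protein genes 0 passed, 2 and 0 when adjusted over the list alone and also with the offset filter, with a list adjusted p of 0.0123 (adjusted p = 0.7 with an estimated correlation in limma). Csn2, the beta-casein gene, ranged from 7.72 to 12.66 in nulliparous and from 12.22 to 14.90 in involution libraries, and Csn1s2b was higher by 1.83 (adjusted p = 0.0594 in limma, and 0.0153 with the offset filter). Of 15 epithelial markers 0 passed, and the list was lower (adjusted p = 0.0105, and adjusted p = 0.7 with an estimated correlation in limma), with Krt19 differing by -1.99. Of 5 measured red blood cell genes Hbb-b1 fell by 2.19, and the list was lower (adjusted p = 0.00151, and adjusted p = 0.7 with an estimated correlation in limma). Without nulliparous replicate 2 the lists of antigen-presenting cells, neutrophils and milk proteins did not pass (adjusted p = 0.269, 0.247 and 0.176), and without involution replicates 1 and 2 those of antigen-presenting cells (0.125 and 0.0622) and neutrophils (0.105 and 0.109). The epithelial list did not pass without nulliparous replicate 1 (0.504) or involution replicate 3 (0.0819). Over all alternatives the adjusted p ran from 1.44e-10 to 0.7, from 0.000721 to 0.719, from 9.73e-08 to 0.91 and from 6.58e-23 to 0.983 for these 4 lists.

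The lists of adipocytes, endothelial cells, pericytes and smooth muscle, T and NK cells, B and plasma cells, mast cells, Schwann cells and skeletal muscle did not pass in camera of limma, with adjusted p of 0.179, 0.366, 0.077, 0.746, 0.278, 0.077, 0.746 and 0.93. Pericytes and mast cells passed downward under median-of-ratios scaling (adjusted p = 0.0333 for both), trimmed-mean scaling (0.0188 for both), the replicate block (0.0378 and 0.00312) and without involution replicate 1 (0.0035 and 0.00459), mast cells also without nulliparous replicate 2 (0.031). B and plasma cells passed upward with the replicate block (0.0378) and endothelial cells downward without involution replicate 1 (0.0162). Over all alternatives the adjusted p ran from 0.00011 to 0.82 for pericytes, from 4.62e-06 to 0.832 for mast cells, from 0.0167 to 0.747 for B and plasma cells and from 3.27e-08 to 0.876 for endothelial cells. In the adipocyte list Plin4, a lipid droplet gene, rose 4.76-fold, and in the T and NK cell list Cd3d, which the offset filter removes, fell by 0.72 while Cd3e, the most abundant member, was higher by 1.56 without passing. Jchain and Igkc, made by plasma cells, were higher by 4.88 and 4.63 with adjusted p of 0.0544 and 0.0621 in limma. They passed with the offset filter (adjusted p = 0.00637 and 0.00789 in limma). Tek and Ptprb of endothelial cells differed by -0.17 and -0.92, Notch3 and Abcc9 of pericytes by -1.55 and -0.56, and Tpsb2 and Mcpt4 of mast cells by -1.75 and -1.96. Mbp of Schwann cells differed by 0.71, and Tnnt3 and Myh4 of skeletal muscle by -0.18 and -2.77. Of these Mbp and Myh4 passed with the offset filter (adjusted p = 0.025 and 0.0166 in limma).

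**Figure D3:**
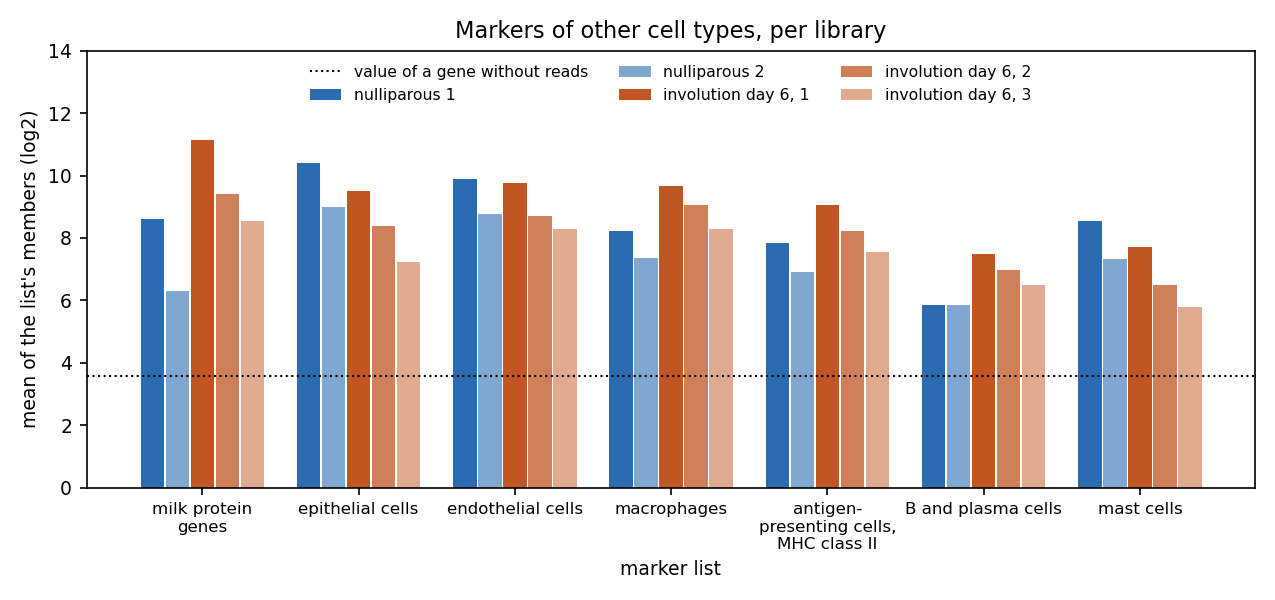
Mean log2 value (vertical axis, from 0) of 7 lists of markers of other cell types (horizontal axis) in each of the 5 libraries. Blue bars are nulliparous and orange bars involution day 6 libraries, and the dotted line is the value of a gene without reads. Macrophage means are 8.22 and 7.37 in nulliparous and 9.65, 9.05 and 8.28 in involution libraries, and epithelial means 10.41, 8.98, 9.51, 8.38 and 7.22 in the same order.

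Genes of tissue dissociation and stress were high in every library, with list means from 13.69 to 14.84. Of 29 members 0 passed, 1 and 2 when adjusted over the list alone and also with the offset filter (camera adjusted p = 0.673 in limma, upward, with a median of 0.12 and a mean of -0.09). Without nulliparous replicate 1 this list was lower at involution (adjusted p = 0.00794 in camera of limma) and without nulliparous replicate 2 it was higher (adjusted p = 0.000455). Egr1 differed by 0.18 and Egr3 by -1.45, which passed with the offset filter (adjusted p = 0.013 in limma). Of 7 measured mitochondrially encoded genes 0 passed, and the list was higher (camera adjusted p = 0.00359 in limma, and adjusted p = 0.808 with an estimated correlation), but not with quantile normalization (adjusted p = 0.345) or without nulliparous replicate 2 (0.0506), from 0.000287 to 0.808 over all alternatives. COX1 and ND6 were higher by 0.31 and 0.64, of which ND6 passed with the offset filter (adjusted p = 0.0452 in limma). Of 45 cytosolic ribosomal protein genes 0 passed with the offset filter and without it, and the list was higher (camera adjusted p = 0.00632 in limma, and adjusted p = 0.928 with an estimated correlation) but turned lower without passing under quantile normalization (adjusted p = 0.345). It did not pass with the replicate block (0.679) or without nulliparous replicate 2 (0.401) or involution replicate 3 (0.618), and its adjusted p ran from 4.97e-06 to 0.928 over all alternatives. Rpl4 differed by 0.10.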

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

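Alternatives with the filter adjusted for the offset, the filters at a mean of 3.7 and 7, the removal of the offset and the 2 covariates were chosen after seeing the data, as were the tests that combine 2 of these choices. Genes higher and lower numbered 322 and 235 in the planned analysis. They stayed within 1.5 times of these counts with 10 added to the unlogged values, quantile normalization, no trend in the prior and array weights. The analysis without a filter removed nothing and is void. Filters moved them to 1018 and 711 (2 log2 units higher), 1058 and 742 (adjusted for the offset, 508 genes shared), 994 and 737 (mean of 3.7) and 963 and 649 (mean of 7). Median-of-ratios scaling gave 540 higher, trimmed-mean scaling 830 and 470, and a robust prior 631 and 417. With the filter adjusted for the offset, removal of the offset gave 1082 and 728, the epithelial covariate 1226 and 839, and the macrophage covariate 1045 and 1139. For all of these counts the cause was not tested. A 2-fold minimum left 179 and 123, and an adjusted p under 0.01 left 0 and 0 in limma, with 5646 genes at an unadjusted p under 0.05.

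Leaving out any 1 library gave 0 and 0 with the planned filter, where the unadjusted p was under 0.05 for 4489 to 5407 genes in limma. With the filter adjusted for the offset it gave 296 and 208 without nulliparous replicate 1, 469 and 242 without nulliparous replicate 2, and 710 and 447, 447 and 299, and 786 and 483 without involution replicates 1, 2 and 3. Between 351 and 492 of these genes were among the 557 of the planned analysis. A nulliparous group of 1 library is assumed to vary like the other group. With the replicate block 0 and 0 genes passed in limma, with 5618 at an unadjusted p under 0.05, and 1817 and 1449 passed with the filter adjusted for the offset. Replicate 3 exists only in the involution group, so the block takes that library out of the comparison. The median difference was -0.0292 both with the block and without involution replicate 3. The block counts therefore rest on 2 libraries per group and lean on the prior (5.46 prior degrees of freedom with the offset filter). Deviations from the group means correlated at 0.58 for replicates 1 and 0.06 for replicates 2. They also correlated at 0.51 for nulliparous replicate 2 and involution replicate 3, whose numbers differ. Deviations of the 2 nulliparous libraries mirror each other, so these values do not show pairing by number. The labels do not say that numbers pair the libraries. For these counts the cause was not tested.

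Biology lists past the threshold numbered 6, between 5 and 9 under the other settings except 11 with the macrophage covariate and 0 with an estimated correlation, and 7 by fry. The 7 were the same 6 and collagen folding and crosslinking. The smallest adjusted p by fry was 0.144 over the marker lists and 0.211 over the quality lists. As signed -log10 of p, positive where higher at involution, these lists reversed. Ribosomal protein genes were at -0.53 with quantile normalization. With the epithelial covariate, epithelial cells were at 0.00723, endothelial cells at 2.79 and stress genes at -2.41. With the macrophage covariate, progenitor genes were at 1.80, milk protein genes at -0.11 and antigen-presenting cells at -1.39, and Ptgs2 differed by 1.84 on the log2 scale, against -1.61 with the epithelial covariate. Stress genes were at -2.10 without nulliparous replicate 1, and with the filter adjusted for the offset at -3.09 without it and 4.25 without nulliparous replicate 2. The covariates remove their own markers by construction, and for the others the cause was not tested. Named genes past the threshold kept their direction under every alternative run. All 51 lost the call when 1 library was left out with the planned filter. Results that passed in neither fit were given no direction. Tests on whole reads were not run, because the reads could not be recovered. Depth limits weakly expressed genes, whose changes the offset shrinks.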

Other observations

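The list of lysosomal genes and all tests in this part were chosen, and several of them revised, only after the values had been seen. Of 64 lysosomal genes listed from textbook knowledge, 34 were higher and 0 lower in limma after Benjamini-Hochberg adjustment, and 51 were higher with the offset filter. The list had a median difference of 0.72 and a camera p of 1.10e-39 in limma, or p = 0.0171 with an estimated correlation, which is not independent evidence because the list was composed after its genes were noticed. Acp5, the tartrate-resistant acid phosphatase gene, rose by 2.63 ± 0.07, Gpnmb by 2.43 ± 0.24, Naglu by 2.13 ± 0.15, the protease gene Lgmn by 2.12 ± 0.10 and Hexa by 1.53 ± 0.11. The list shares 3 genes, the cathepsins Ctsb, Ctsk and Ctsl, with the matrix proteases.

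Further genes with large differences stand outside the fixed lists and were chosen after their values were seen. Mgp, the matrix Gla protein gene, had the smallest adjusted p, 0.0137 in limma, and rose by 2.54 ± 0.06. Epas1, which encodes a hypoxia-inducible factor, rose by 2.35 ± 0.11 and Cpxm1, a carboxypeptidase-like gene, by 2.76 ± 0.19. Mlana rose by 3.78 ± 0.37 and Rab27a by 3.58 ± 0.31, while the pigment enzyme genes Tyr, Tyrp1 and Dct lay between 3.56 and 3.90 in all 5 libraries, near the 3.57 of a gene without reads. Scg3, a secretory granule gene, fell by 2.92 ± 0.12 and the glutamate receptor gene Gria1 by 2.12 ± 0.19. Igha, the constant region gene of IgA, was higher by 5.92 ± 0.86, with an adjusted p of 0.0588 in limma and 0.0071 with the offset filter. Genome span was compared over the 15860 genes of the offset filter that had one, which left 197 called lower and 311 called higher genes. The lower genes spanned a median of 39.2 kb and the higher genes 20.1 kb, against 21.4 kb over all 15860. Span and log2 difference were weakly related across genes (Spearman's rho -0.08, and genes are not independent replicates).

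RNA from macrophages, which are rich in lysosomes, is one explanation of the lysosomal pattern. The sort for PDGFRa should remove them, yet Lyz2 reached 12.37 in involution replicate 1, and the marker mean was 9.65, 9.05 and 8.28 in involution and 8.22 and 7.37 in nulliparous libraries, with 0 of 14 markers past the threshold and 2 with the offset filter. With the macrophage marker mean as a covariate, fitted to the genes of the offset filter, 47 of all 64 genes were higher past the threshold and 0 lower in limma. Without the covariate 51 were higher with that filter. The median difference of the 64 genes was 0.73 with the covariate and 0.72 without it. Of the 34 genes called with the planned filter 33 stayed past the threshold, but the offset filter calls more genes, so this count adds little. A covariate leaves only 2 residual degrees of freedom. Over the 3 involution libraries the median SD was 0.083 for all 64 genes and 0.656 for the 14 macrophage markers, and no lysosomal gene of the list is among those markers. These values argue against macrophage RNA as the whole cause, so a rise within the sorted fibroblasts may be considered as a hypothesis, with other cell types that hold even shares in all libraries left open.

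The milk protein list was higher and the epithelial list lower in camera of limma at the preset correlation, but 0 of 8 and 0 of 15 members passed, 2 and 0 of them with the offset filter, and both lists had an adjusted p of 0.7 with an estimated correlation. The milk protein list was also lost without nulliparous replicate 2 (adjusted p = 0.176, from 9.73e-08 to 0.91 over all alternatives), and the epithelial list without nulliparous replicate 1 and without involution replicate 3 (0.504 and 0.0819, from 6.58e-23 to 0.983). The epithelial mean differed by -1.325 ± 1.005 (SE) and the milk protein mean by 2.246 ± 1.301, which argues against more epithelial cells in the involution libraries, although the SEs are wide. The milk protein mean minus the epithelial mean was -1.81 and -2.68 in nulliparous libraries and 1.62, 1.04 and 1.32 in involution libraries, so the groups were 2.848 apart. More milk protein RNA per epithelial cell is consistent with this, and milk RNA free in the cell suspension stays open, as it was not tested.

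All 9 Wnt and growth factor genes that fell stayed lower past the threshold in limma with the epithelial marker mean as a covariate. The fit used the offset filter, and 487 of the 557 genes of the planned analysis were called in it, so this count adds little. A covariate also leaves only 2 residual degrees of freedom. The difference that changed most was that of Ptn, from -4.13 to -3.36, and that of Wnt4 went from -2.61 to -2.75. These sizes argue against fewer epithelial cells in the involution libraries as the whole cause. A second explanation is less of their RNA per epithelial cell, in which case the genes should follow the epithelial markers within the groups, whose slopes on their own mean ran from 0.635 to 1.27. The median slope was 0.0495 for Wnt4, Wnt5a, Wnt6, Tcf7, Fzd4, Rspo1 and Fgf10, and 0.546 for Areg and Ptn. Each of the first 7 lay over 2 SE, by its own SE, under the lowest of the 15 marker slopes. For these 7 genes this argues against an epithelial source that follows those markers. The slopes of Areg and Ptn, 0.507 ± 0.225 (SE) and 0.586 ± 0.080, did not lie under it in this way. Slopes of the 8 milk protein genes ran from 0.213 ± 0.152 (SE) to 2.21, with a median of 1.40. Only Wnt4, Wnt6 and Fgf10 lay over 2 SE under that slope by their own SE, and 0 of 9 with the SE of both slopes counted, so for all 9 genes epithelial cells and fibroblasts cannot be told apart as the source, and a fall within the fibroblasts may be considered only as a hypothesis.

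Earlier tests were replaced or dropped. Single libraries were first compared: involution replicate 1 exceeded replicate 3 by a median of 0.04 in the 34 lysosomal genes and 1.31 in the macrophage markers. Involution replicate 1 lay 0.95 to 4.25 under nulliparous replicate 2 in 7 growth factor and Wnt genes, while epithelial markers were higher by a median of 0.40. Slopes were first held against 1, which left 8 of the 9 genes under the bound and only Areg open. The lowest marker slope moved Ptn to the open part. The lowest milk protein slope would move 4 more there, and counting both SEs would also move Wnt4, Wnt6 and Fgf10. The lowest milk protein slope is that of Csn1s2b. These later steps therefore stand above only as a limit, and the reading rests on the marker slopes. The SD was first compared for the 34 called genes only (0.0657), which the call itself favours. A test for melanocytes rested on the pigment enzyme genes given above, which lie too near the floor to decide.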
